A study of Mus musculus with 4 samples.

How the data were processed

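RNA was measured in 4 libraries from iMOP cells, an immortalized mouse line of otic progenitors, with 2 libraries in each of 2 groups. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was depleted, and libraries were made with a stranded kit. Per the submitters' processing notes, the tools included HISAT2, SAMtools, featureCounts and DESeq2 and the build was mm10. Their versions and settings, the gene annotation and the strand setting of the counting were not given in the sources used here, so reads of overlapping or antisense genes could have been assigned to either gene.

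The authors deposited raw counts per gene, one file per library, with ribosomal RNA genes included. The authors also deposited RPKM values, which scale each count by gene length and by the total counts of the library. Dividing counts by RPKM and by the library total gave the same gene length in every library, within a relative tolerance of 0.001, for 17709 of the 17709 genes checked, so those totals included the ribosomal RNA counts. Each file held 49997 gene rows, of which 23768 had at least 1 count in any library. Gene positions and GC content came from the GENCODE M21 annotation and genome of the same build, in which 19574 of those genes had a unique symbol. A GC value was available for 93.9% of the tested genes.

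Total counts were 3150354 and 32913243 in the libraries labelled proliferating and 27424909 and 8368169 in those labelled neuron. After 7 ribosomal RNA and rRNA-like genes were set aside (Rn18s-rs5, Lars2, Mir6236, Gm15564, AY036118, mt-Rnr1 and mt-Rnr2), 292302, 614465, 3241915 and 617872 counts remained in the same order. A count of 0 allows, at 3 counts, a level of up to 10.3, 4.88, 0.925 and 4.86 CPM of those remaining counts. Intervals for shares are 95% Wilson intervals. These intervals and limits cover counting error alone, since reads are not independent molecules.

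Raw counts of the 2 groups were compared with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, TMM scaling and filterByExpr, which left 11525 genes. Adjusted p-values are Benjamini-Hochberg values over the tested genes, with a threshold of 0.05. Log2 CPM values used a prior count of 2. Gene lists were tested two-sided with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Members that did not pass the count filter were not tested, and counts of called genes in a list are out of its tested members. The tests, their alternatives, 24 gene lists and the rule for naming genes were chosen before the data were examined. The rule named Chd7, Ctcf, Rad21 and Myc, then up to 8 genes per direction with the largest fold change among those past the threshold with a mean log2 CPM of at least 4 and no overlap between groups. Predicted genes, clone names, pseudogenes and small RNAs were left out. From each list it named up to 3 members past the threshold in the list's majority direction and up to 1 in the other, with a mean log2 CPM of at least 1, or the 2 members with the highest mean where none passed. The rule was applied to both fits described next, and 2 genes that it named are not reported here.

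The edgeR model with the replicate number as a factor was among the alternatives chosen beforehand. After the data were examined, the libraries numbered 1 and those numbered 2 were read as 2 library sets, because they differed in small RNA content and in GC dependence, and that model is called the fit with the library-set term and given beside the fit with group alone. It left 1 residual degree of freedom in place of 2. In the results, list medians, camera values and fold changes of genes not called are from the fit with group alone unless another setting is named. Within-set log2 ratios were differences of log2 CPM, centred on the median of all tested genes. A GC correction and a gene length correction, both added after the data were examined, subtracted, in each library, a spline with 5 degrees of freedom fitted to the deviation of log2 CPM. A list's within-set median was ranked among 10000 random lists matched on mean expression.

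Both edgeR fits and camera were tested on simulated data, while the corrections, the random lists and the other tools were not. With 50 genes changed at each fold among 11015 tested, the fit with group alone recovered 0 genes at folds of 2, 4, 8 and 16. The fit with the library-set term recovered 0, 8, 27 and 39 genes at those folds, with 5 unchanged genes called. These counts were drawn from that fit's own means and spread, with the same group effect in both sets. In the deposited data only 52.6% of tested genes had the same sign in both sets. The run therefore cannot give the power or the share of false calls in the deposited data. A simulated glycolysis list changed 4-fold was found by camera among 10162 genes, with 0 other lists called. Genes were drawn independently there, so that run could not check the preset correlation.

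The alternatives were DESeq2 size factors, upper-quartile scaling and library totals in edgeR, the Wald test of DESeq2 1.42.0, limma voom, limma trend on log2(RPKM + 0.1) and on log2(RPKM + 1), and 2 other count filters. Further alternatives were a threshold of 0.01, a test against a fold change of 2, the replicate number as a factor, the removal of mitochondrial, ribosomal and small RNA genes, and each library left out in turn.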

Results

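Gene expression was compared between libraries labelled proliferating and libraries labelled neuron, all from iMOP cells, an immortalized line of mouse otic progenitors. The labels give 20 ng/ml bFGF, a growth factor, for the first group, and Neurobasal medium with 1 µM K03861, an inhibitor of the cell cycle kinase CDK2, for the other. The proliferating and neuron libraries are named by these labels throughout, and several markers of division and of neurons went against them. Each group had 2 libraries, numbered 1 and 2. The labels do not say that these came from separate cultures, so p-values of the gene tests measure only the spread between these samples. Those of camera at its preset correlation set list genes against other genes, treated as nearly independent, and do not measure that spread. Total counts were 3150354 and 32913243 in the proliferating libraries and 27424909 and 8368169 in the neuron libraries. The 18S ribosomal RNA gene Rn18s-rs5 and 6 other ribosomal RNA or rRNA-like genes took 90.7% of the counts in proliferating 1 (95% Wilson binomial interval 90.69 to 90.75), 98.1% in proliferating 2 (98.13 to 98.14), 88.2% in neuron 1 (88.17 to 88.19) and 92.6% in neuron 2 (92.60 to 92.63). The counts outside these genes numbered 292302, 614465, 3241915 and 617872 in the same order, and 6196, 7013, 13259 and 6817 genes had at least 10 counts.

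The libraries resembled each other by number more than by group. Across genes, which are not independent replicates, the Pearson correlation of log2 CPM was 0.82 between proliferating 1 and neuron 1 and 0.84 between proliferating 2 and neuron 2, against 0.56 between the proliferating libraries and 0.61 between the neuron libraries. The first principal component held 71.4% of the variance and separated the numbers. The non-coding RNAs Rn7sk, Rpph1 and Rmrp made up 4.78% and 2.37% of the remaining counts in the libraries numbered 1 and 0.405% and 0.352% in those numbered 2. Mitochondrial messenger RNAs made up 2.35% and 2.53% in the libraries numbered 1 and 10.6% and 14.6% in those numbered 2. The libraries are therefore also described as set 1 and set 2, each with 1 library per group.

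With group alone in the model, edgeR's quasi-likelihood test called 0 genes higher and 0 lower in the libraries labelled neuron, and 130 of 11525 genes had an unadjusted p under 0.05. DESeq2, run on 23768 genes, also called 0, with 191 under that unadjusted p. Limma called 0 on log2(RPKM + 0.1), on log2(RPKM + 1) and with voom, with 158, 120 and 81 genes under it. Chd7, the chromatin remodeller named in the study's title (chromosome 4, 8690406 to 8867659 in mm10), had 273 and 367 counts in the proliferating libraries and 1582 and 282 in the neuron libraries. Its log2 fold change, neuron over proliferating, was -0.57 (SE 1.00, 2 libraries per group). Ctcf, which encodes the main insulator protein of mammals (chromosome 8, 105636568 to 105682922), had 31, 65, 368 and 39 counts and a log2 fold change of -0.22 (SE 0.96). Neither Chd7 nor Ctcf differed by more than the spread between replicates. Both values were positive on log2(RPKM + 0.1), at 0.46 and 0.75. On that scale the median of all genes was 0.74, against 0.09 in edgeR with group alone. Within set 1 and set 2, the log2 ratios were -1.06 and -0.26 for Chd7 and -0.03 and -0.60 for Ctcf. The cohesin subunit Rad21 had a log2 fold change of 0.70 (SE 0.98) and Myc one of 1.12 (SE 1.12), also within the spread.

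With a term for the library set, which is the fit with the replicate number as a factor, edgeR called 42 genes higher and 15 lower in the libraries labelled neuron. Of all tested genes, 52.6% had the same sign in both sets, and the Spearman correlation of the set ratios across genes was 0.16. Genes of cell division were prominent by count, since 15 of the 42 higher genes belonged to the S phase or mitosis lists, against 0.419 expected by chance. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361) had 15 and 97 counts in the libraries labelled proliferating and 1947 and 791 in those labelled neuron, and rose by 3.36 on the log2 scale (SE 0.66, adjusted p = 9.00e-04 in edgeR). Top2a, the topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), rose by 3.11 (SE 0.64, adjusted p = 0.00197 in edgeR). Wdr3, a gene of ribosome assembly, rose by 2.84 (SE 0.66) and Trim33 by 2.74 (SE 0.71). The log2 ratios of Trim33 were 0.90 in set 1 and 4.33 in set 2. Trim33 (chromosome 3, 103279293 to 103358775) lies near Dennd2c (103102604 to 103169769) and Bcas2 (103171655 to 103179166). These 2 genes, chosen after their values were seen, were also called higher, and a shared cause was not tested. Trim33 lost its call with several settings, among them DESeq2 size factors (2.62, adjusted p = 0.0539 in edgeR), limma voom (2.85, adjusted p = 0.0663), a length correction (2.57, adjusted p = 0.0552 in edgeR) and a GC correction (2.33, adjusted p = 0.132 in edgeR). No called gene that was lower met the level of the naming rule for the largest changes. With the GC correction 27 genes were called higher and 11 lower, 33 of them among the 57. With DESeq2 size factors the set-term counts were 43 and 24. With library totals alone they were 3 and 0, and the median of all genes was 1.08, against 0.07 with TMM scaling.

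**Figure D1:**
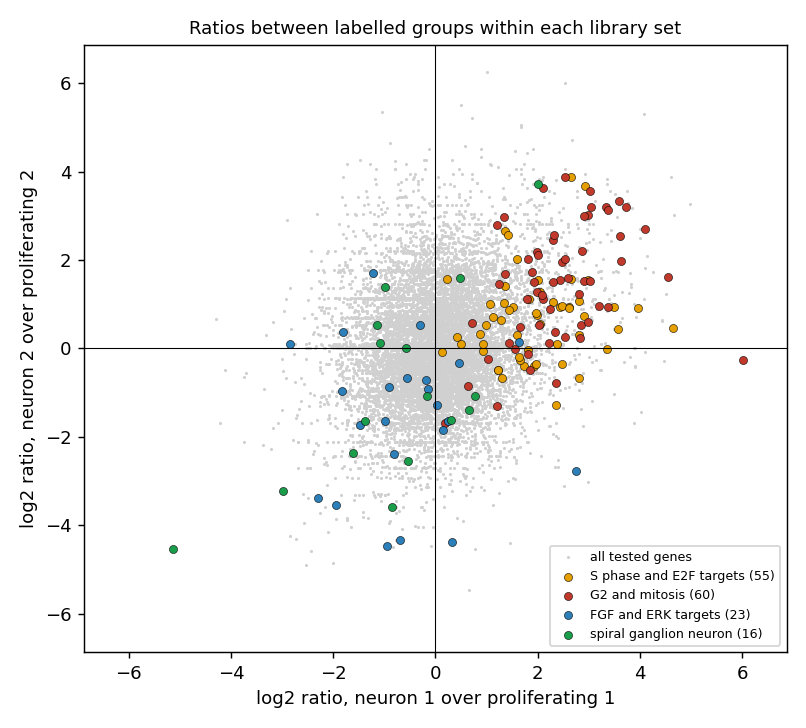
Each point is a tested gene, with the log2 ratio of neuron 1 over proliferating 1 on the horizontal axis and of neuron 2 over proliferating 2 on the vertical axis, both centred on the median gene. Of 60 G2 and mitosis genes 51 lie above 0 on both axes and 0 lie below 0 on both.

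Among 60 tested G2 and mitosis genes, 13 rose and 0 fell with the library-set term, and 39 rose when adjusted over the list alone. Bub1, a spindle checkpoint kinase, rose by 3.60 (SE 0.79), the mitotic kinesin Kif20b by 3.59 (SE 0.75) and the kinetochore gene Cenpf by 3.58 (SE 0.69). Kif20b missed the threshold after the GC correction, at 2.67 (adjusted p = 0.0509 in edgeR). So did the called genes Kif11, Ttk, Ncapg, Knl1 and Smc2 (adjusted p = 0.062, 0.0689, 0.163, 0.185 and 0.338 in edgeR). The median log2 fold change of the list was 2.05 with group alone (camera adjusted p = 1.11e-32, and adjusted p = 0.365 with an estimated correlation), and it was 2.33 in set 1 and 1.51 in set 2. Of 55 S phase and E2F targets, 2 rose with the library-set term, 10 when adjusted over the list alone, and 40 were higher in both sets. Pola1, a subunit of DNA polymerase alpha, rose by 3.55 (SE 0.72), and Brca1, a DNA repair gene named after its values were seen, by 3.63 (SE 0.86). The list median was 1.38 (camera adjusted p = 5.11e-17, and adjusted p = 0.365 with an estimated correlation), with 1.93 in set 1 and 0.71 in set 2.

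Few genes of neurons rose in the libraries labelled neuron. Of 23 pan-neuronal genes, 0 rose and 1 fell with the library-set term. That gene, the neuronal growth-associated Stmn2, chosen after its values were seen, fell by 3.50 on the log2 scale (SE 0.79). Map1b and Map2, microtubule proteins of neurons, had log2 fold changes of -0.78 and -0.70 with group alone. The list median was -0.25 (camera adjusted p = 0.0497, and adjusted p = 0.802 with an estimated correlation), and the call ended without proliferating 1 (adjusted p = 0.152), without proliferating 2 (0.351) and without neuron 2 (0.952), and with the library-set term (0.059). Of 35 spiral ganglion neuron genes 16 were tested. With the library-set term 0 rose and 2 fell, and 1 rose and 3 fell when adjusted over the list alone. Ebf1, a transcription factor, fell by 3.10 (SE 0.69), and Nhlh1, a neuronal transcription factor chosen after its values were seen, fell by 5.44 (SE 0.93). Ebf1 lost its call with limma on the RPKM scales, at -1.67 on log2(RPKM + 0.1) (adjusted p = 0.133) and -0.69 on log2(RPKM + 1) (adjusted p = 0.0995). The spiral ganglion median was -0.86 (camera adjusted p = 4.18e-04, and adjusted p = 0.365 with an estimated correlation), with adjusted p = 0.078 without proliferating 2. Nrxn3, a presynaptic adhesion gene, rose by 3.30 (SE 0.76) as the 1 called gene of 26 in the synapse list, whose median was -0.41 (camera adjusted p = 0.372). Nrxn3 lost its call with several settings, among them limma voom, at 3.21 (adjusted p = 0.0923), and limma on log2(RPKM + 0.1) and log2(RPKM + 1), at 0.95 and 0.14 (adjusted p = 0.0772 and 0.222). The voltage-gated channels had 0 called genes of 19. Their median was -0.26 with group alone (camera adjusted p = 0.622) and 0.066 with the library-set term. Kcnd3 was at 0.24 and Scn8a at -0.59 with group alone. The axon guidance list had 0 called of 34 and a median of -0.32 (camera adjusted p = 0.299), with -1.02 for Sema6a and -1.01 for Dcc.

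Of 23 FGF and ERK targets, 0 rose and 1 fell with the library-set term, and 4 fell when adjusted over the list alone. The called gene was Spry2, an inhibitor of FGF signalling that FGF induces, which fell by 2.81 on the log2 scale (SE 0.67). Spry2 lost its call with several settings, among them limma voom, at -2.81 (adjusted p = 0.0663), and limma on log2(RPKM + 0.1) and log2(RPKM + 1), at -1.59 and -0.88 (adjusted p = 0.147 and 0.0928). The list median was -0.91 (camera adjusted p = 1.16e-06, and adjusted p = 0.365 with an estimated correlation), at -0.69 in set 1 and -1.27 in set 2, and without proliferating 2 the median was -0.39 and the call ended (adjusted p = 0.197). In the Notch list 0 of 24 genes were called. Its median was -0.53 (camera adjusted p = 0.00251, and adjusted p = 0.802 with an estimated correlation), with -0.32 for Notch2 and -0.62 for Dtx4, and it was 0.98 without proliferating 1 (adjusted p = 0.959) and lost its call without neuron 2 (adjusted p = 0.266). In the otic progenitor list 0 of 17 genes were called, and its median was -0.75 (camera adjusted p = 0.00808, and adjusted p = 0.365 with an estimated correlation). The intermediate filament genes Vim and Nes had values of -1.76 and -0.42, and the list's call ended without proliferating 1 (adjusted p = 0.152), proliferating 2 (0.167) or neuron 2 (0.239).

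Of 26 glial genes 11 were tested. With the library-set term 1 rose and 2 fell, and 1 rose and 5 fell when adjusted over the list alone. The oligodendrocyte lineage factors Olig2 and Olig1 fell by 3.39 (SE 0.68) and 2.66 (SE 0.72), while the water channel gene Aqp4 rose by 2.89 (SE 0.78). Olig1 and Aqp4 lost their calls with several settings, among them the GC correction, at -2.23 and 2.26 (adjusted p = 0.163 and 0.211 in edgeR), and limma voom, at -2.52 and 3.16 (adjusted p = 0.128 and 0.171). Aqp4 also lost its call with DESeq2, at 2.95 (adjusted p = 0.102). The list median was -1.62 (camera adjusted p = 0.00107, and adjusted p = 0.365 with an estimated correlation), and it was 0.78 without proliferating 1 (adjusted p = 0.723), with adjusted p = 0.0892 without neuron 2. Aqp4 was also the 1 called gene of 10 in the supporting cell list, with a median of -0.48 (camera adjusted p = 0.0875). The hair cell list had 0 called of 6 and a median of 0.31, opposite to the direction of the test (camera adjusted p = 0.823). Myo6 was at -0.75 and Triobp at 0.52. The mesenchyme list had 0 called of 5 and a median of -0.11 (camera adjusted p = 0.823), with -0.88 for Sparc and -1.27 for Pou3f4. None of the 15 immune cell genes had enough counts to be tested.

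The insulator and cohesin list had 0 called of 22 genes and a median of 1.22 (camera adjusted p = 0.0129, and adjusted p = 0.802 with an estimated correlation), with 1.57 for the cohesin loader Nipbl. That median was -0.17 without neuron 2 (adjusted p = 0.828), the call ended without proliferating 1 (adjusted p = 0.73), and with the library-set term the median went from 1.09 to 0.48 after the GC correction (adjusted p = 0.204). The CHD and SWI/SNF remodellers had 0 called of 35 and a median of 0.05, opposite to the direction of the test (camera adjusted p = 0.823). Smarcc1 was at -0.28. The CDK inhibitors and cyclins D had 0 called of 18 and a median of -0.10 (camera adjusted p = 0.622), with -0.26 for Cdk4 and -0.21 for Ccnd2. The p53 targets had 0 called of 21 and a median of 0.38, opposite to the direction of the test (camera adjusted p = 0.521), with 1.14 for Mdm4 and -0.95 for Ddit4.

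The medians of 5 metabolic and biosynthetic lists had opposite signs in the sets, a difference that was not tested. The ribosome biogenesis and MYC targets had 0 called of 43 genes and a median of 0.66 (camera adjusted p = 0.0437, and adjusted p = 0.802 with an estimated correlation), at 1.17 in set 1 and -0.31 in set 2, with 1.05 for Ncl and 1.07 for Npm1. That median was -0.43 without neuron 1 (adjusted p = 0.991), and the call ended without proliferating 1 (adjusted p = 0.617). The cholesterol synthesis genes had 0 called of 23 and a median of -0.14 (camera adjusted p = 0.0193, and adjusted p = 0.802 with an estimated correlation), at 0.79 in set 1 and -1.70 in set 2, with -0.80 for Hmgcs1. It was 0.40 without proliferating 2 (adjusted p = 0.857) and 0.13 without neuron 2 (adjusted p = 0.266). The ATF4 and unfolded protein response list had 0 called of 27 and a median of 0.67 (camera adjusted p = 0.0719), at 1.41 and -0.36 in the sets, with -0.66 for Hspa5 and 1.40 for Hsp90b1. Glycolysis had 0 called of 20 and a median of 0.66 (camera adjusted p = 0.318), at 0.96 and -0.11, with 1.16 for Pkm and 0.27 for Ldha. Oxidative phosphorylation had 0 called of 47 and a median of 0.06, opposite to the direction of the test (camera adjusted p = 0.369). Its medians in the sets were 0.52 and -0.68, with 0.12 for Atp5a1 and 0.40 for Atp5b.

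Among families read from gene symbols, 44 replication-dependent histone genes had a median of 1.78 (camera adjusted p = 2.26e-05, and adjusted p = 0.578 with an estimated correlation), at 1.59 in set 1 and 0.66 in set 2, with 0 called. It was -2.63 without neuron 1 (adjusted p = 0.0536) and lost its call without proliferating 2 (adjusted p = 0.935). The 81 cytosolic ribosomal protein genes had a median of -0.39 (camera adjusted p = 4.72e-05, and adjusted p = 0.578 with an estimated correlation). It was 0.17 with library totals alone, where the median of all genes was 0.86, and 0.27 without proliferating 1. The 39 small RNAs had a median of -0.74 (camera adjusted p = 8.84e-05, and adjusted p = 0.578 with an estimated correlation), at 1.20 without proliferating 1 (adjusted p = 0.53) and with adjusted p = 0.718 without neuron 2. The 10 mitochondrial messenger RNAs had a median of 0.33 (camera adjusted p = 0.921). Across genes, log2 fold change had a Spearman correlation of 0.15 with gene length and of -0.33 with GC content.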

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

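The GC and length corrections, the filter of 10 counts per set and the other settings run together with the replicate block were chosen after the data were examined; the block by itself was planned. With group alone, 0 genes were called higher and 0 lower under every scaling, filter, tool and threshold run. These counts cannot show that the result is stable. In simulated data the edgeR fit with group alone recovered 0 of 50 changed genes even at a fold of 16, and the other tools were not simulated. The stricter threshold and the test against a minimum fold change could not have called more genes than the main fit. The replicate block, which is the same model as the library-set term, gave 42 and 15. The labels do not say that the numbers pair samples, and with 2 pairs this is a hint from the data: the differences between the numbers correlated at 0.69 between the groups, and at 0.57 with no filter and 0.60 with at least 10 counts in every library. Without 1 library the lone sample of a group was assumed to vary like the other group, and the library-set term left no residual degrees of freedom, so that fit has no test there.

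With the library-set term, the 42 higher and 15 lower genes became 3 and 0 with library totals, 25 and 7 with limma voom, 774 and 8 on log2(RPKM + 0.1), 922 on log2(RPKM + 1), 8 and 5 with at least 10 counts in every library, 7 and 3 against a fold change of 2, 69 and 39 without mitochondrial, ribosomal and small RNA genes, 64 and 28 with the length correction and 17 and 7 at a threshold of 0.01. The higher genes were 27 with the GC correction. The lower genes were 24 with DESeq2 size factors and with upper-quartile scaling, 27 with DESeq2, 9 with no filter and 23 with genes under 10 counts in either set left out. The median of all genes was 0.07 in the main fit with the library-set term and 1.08 with library totals. It was 0.74 and 0.26 on the RPKM scales, which divide by totals that include ribosomal RNA. The cause of these differences was not tested.

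Camera called 11 lists, 0 with an estimated correlation, 0 with fry, and 5 to 12 without 1 library. It called 3 families, and 0 with an estimated correlation. The G2 and mitosis median of 2.05 and the S phase median of 1.38 kept their direction and camera call with DESeq2 size factors, library totals, the block and both corrections. Upper-quartile scaling was not run for the lists. Both medians kept their direction with each library left out. Both lists had adjusted p = 0.365 in camera with an estimated correlation and 0.754 with fry. The correlation of length with fold change ranged from -0.039 to 0.24 without 1 library.

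Signs turned as follows, and the cause was not tested. With library totals, the values were Ctcf 0.64, Map1b 0.55, Nes 0.61, Cdk4 0.39, Ccnd2 1.61, Hspa5 1.21, Smarcc1 0.94, Hmgcs1 0.97, Pou3f4 0.17, pan-neuronal list 0.43, synapse and vesicle release list 0.092, spiral ganglion neuron list 0.048, CDK inhibitors and cyclins D list 0.48, axon guidance list 0.32, cholesterol synthesis list 0.97, mesenchyme and fibroblast list 0.29 and cytosolic ribosomal proteins 0.17. On log2(RPKM + 0.1) they were Chd7 0.46, Ctcf 0.75, Map1b 0.56, Map2 0.28, Scn8a 0.18, Nes 0.64, Notch2 0.86, Dtx4 0.37, Cdk4 0.39, Ccnd2 1.39, Hspa5 1.22, Smarcc1 0.97, Dcc 0.022, Hmgcs1 0.83, Myo6 0.20 and Sparc 0.14. On log2(RPKM + 1) they were Chd7 0.23, Ctcf 0.40, Map1b 0.52, Map2 0.12, Nes 0.54, Notch2 0.29, Dtx4 0.13, Cdk4 0.33, Ccnd2 0.82, Hspa5 1.14, Smarcc1 0.85, Hmgcs1 0.78, Sparc 0.10 and Pou3f4 0.017. With limma voom they were Ccnd2 0.31, Hspa5 0.18 and Atp5a1 -0.024. With DESeq2 size factors they were Atp5a1 -0.019, CHD and SWI/SNF remodellers list -0.095 and oxidative phosphorylation list -0.079. With the replicate block they were Ccnd2 0.33, Hspa5 0.13, voltage-gated channels list 0.066 and CHD and SWI/SNF remodellers list -0.033, and with the block and GC correction Notch2 0.31, Ccnd2 0.24, voltage-gated channels list 0.059 and CDK inhibitors and cyclins D list 0.097. None of these genes was called.

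Without 1 library, log2 fold changes that turned ranged over Map1b -1.46 to 0.47, Scn8a -1.14 to 0.081, Notch2 -1.18 to 1.28, Cdk4 -2.12 to 0.33, Ccnd2 -1.03 to 1.85, Hspa5 -1.53 to 1.84, Npm1 -0.48 to 2.91, Nipbl -0.23 to 2.25, Smarcc1 -0.86 to 0.64, Pkm -1.17 to 2.08, Ldha -0.85 to 1.33, Atp5a1 -0.57 to 0.35, Atp5b -0.85 to 0.84, Hmgcs1 -1.60 to 1.05, Myo6 -1.59 to 0.036 and Triobp -2.48 to 3.01. Medians that turned ranged over pan-neuronal list -1.28 to 0.099, synapse and vesicle release list -1.46 to 0.75, voltage-gated channels list -1.14 to 1.07, Notch pathway list -2.25 to 0.98, CDK inhibitors and cyclins D list -0.85 to 0.57, p53 targets list -0.17 to 0.41, ATF4 and unfolded protein response list -0.47 to 0.82, ribosome biogenesis and MYC targets list -0.43 to 0.90, insulator and cohesin list -0.17 to 1.80, CHD and SWI/SNF remodellers list -0.28 to 0.36, axon guidance list -0.94 to 1.07, glycolysis list -1.10 to 1.09, oxidative phosphorylation list -0.86 to 0.26, cholesterol synthesis list -1.92 to 0.40, hair cell list -0.40 to 1.94, supporting cell list -0.91 to 0.30, glia and Schwann cell list -2.39 to 0.78, mesenchyme and fibroblast list -0.47 to 1.94, replication-dependent histones -2.63 to 6.09, cytosolic ribosomal proteins -1.19 to 0.27, small RNAs -2.35 to 1.20 and mitochondrially encoded messenger RNAs -2.29 to 2.27. Values that kept their sign but moved by over 1.5 times without 1 library ranged over Chd7 -0.92 to -0.40, Ctcf -0.53 to -0.13, Rad21 0.081 to 1.06, Myc 0.25 to 1.44, Map2 -1.42 to -0.39, Kcnd3 0.091 to 0.24, Vim -2.41 to -0.65, Nes -0.88 to -0.13, Dtx4 -0.98 to -0.40, Mdm4 0.20 to 1.64, Ddit4 -3.57 to -0.29, Hsp90b1 0.36 to 2.81, Ncl 0.072 to 2.47, Sparc -1.34 to -0.77, Pou3f4 -1.87 to -0.34, spiral ganglion neuron list -1.57 to -0.69, otic progenitor list -1.28 to -0.23 and FGF and ERK targets list -1.51 to -0.39. Among single genes, lists and families other than Chd7, Ctcf, the G2 and mitosis list and the S phase list, 592 planned and 242 added comparisons stayed the same. A further 34 and 53 kept the direction but lost the call, 7 and 5 gained one, and 105 and 4 turned. Staying the same meant an unchanged direction and side of the threshold or, for counts of list members, a change of at most 1.5 times. Such counts were included for every tested list, and 14 added ones moved by more or from 0. With group alone 0 genes were called under any setting, so a side of the threshold kept by single genes there is no sign of stability. Whether depth sets these ranges was not tested, and the libraries other than neuron 1 held 292302 to 617872 counts outside ribosomal RNA.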

Other observations

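The tests of exchanged labels and of the culture condition were chosen after the result was seen. Other genes called with the library-set term, chosen here after their values were seen, add to both directions. The neuronal repressors Scrt1 and Scrt2 were lower by -3.81 (SE 1.02) and -4.40 (SE 1.16) on the log2 scale in the libraries labelled neuron, Myt1, a neuronal zinc finger gene, by -2.85 (SE 0.66), and Id3, an inhibitor of differentiation, by -3.51 (SE 0.78). Scrt1 had 48 and 3 counts in the proliferating libraries and 38 and 0 in the neuron libraries. Scrt2 had 34 and 2 counts against 17 and 0, so both lay near the floor in set 2. Scrt1 and Scrt2 missed the threshold after the GC correction, at -3.36 (adjusted p = 0.0824 in edgeR) and -3.99 (adjusted p = 0.062 in edgeR). The matrix gene Tnc was lower by -3.35 (SE 0.68). Among higher genes, Hhip, which binds hedgehog ligands, was at 4.58 (SE 1.12), with 3.86 and no call after the GC correction (adjusted p = 0.0684 in edgeR), the glypican gene Gpc6 at 3.02 (SE 0.78) and the chaperone gene Clu at 2.91 (SE 0.70).

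Several otic and neural crest markers had almost no counts in any of the libraries. In the order proliferating 1, proliferating 2, neuron 1 and neuron 2, Pax2 had 0, 0, 1 and 0 counts, Oc90 had 0, 0, 1 and 0, and Gata3 had 1, 0, 2 and 0. Pax8, Neurog1, Isl1 and Sox10 had 0 counts in each library, which allows up to 10.3, 4.88, 0.925 and 4.86 CPM of the counts outside ribosomal RNA. Olig2 had 68, 168, 120 and 7 counts and Pou3f4 had 46, 238, 528 and 43.

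Of 60 G2 and mitosis genes, 13 rose and 0 fell with the library-set term in the libraries labelled neuron, for which the labels give a CDK2 inhibitor, while 0 were called with group alone and the list was not called with an estimated correlation (adjusted p = 0.365, and 0.825 with the library-set term) or with fry (adjusted p = 0.754). GC content and gene length are argued against as the whole cause, since the list median was 1.83 after the GC correction and 2.08 after the length correction, against 2.06 before. Several called genes of the list, Kif20b among them, still lost their call after the GC correction. Exchanged group labels stay open. FGF and ERK targets, which bFGF should raise, had a median of -0.62 after the GC correction. The otic progenitor medians were below 0 in both sets (-0.98 and -1.12), and both results are opposite to what an exchange predicts. The pan-neuronal (-0.11 and -0.995) and spiral ganglion (-0.72 and -1.24) medians in the sets go with one. None of these lists was called with an estimated correlation. With group alone and without 1 library, the otic progenitor median ranged from -1.28 to -0.23 and the pan-neuronal median from -1.28 to 0.099. With group alone the FGF median was -0.39 without proliferating 2, against -0.91 with it, and the list was not called with an estimated correlation (adjusted p = 0.365, and 0.825 with the library-set term) or with fry (adjusted p = 0.754). The culture condition needs the difference in both sets, where the smaller median was 1.51, but an exchange predicts the same, so the 2 explanations cannot be told apart.

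The libraries parted by number more than by group. The difference of set 1 from set 2 had a Spearman correlation with GC content of 0.63 across genes in the proliferating libraries and 0.82 in the neuron libraries, consistent with a GC-dependent difference in library preparation or amplification between the sets. What set it off is open, since the labels name no batch.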
